A study of Danio rerio with 8 samples.

How the data were processed

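Total RNA was extracted from zebrafish liver with Trizol and labelled with a two-colour protocol of Agilent, per the labels' protocols. The 8 arrays form a loop in which the labels name the RNA sample and dye of each channel. The authors deposited 1 log2 ratio per probe and array, and limma is the tool named in the submitters' processing notes, with no version. The background correction, the normalization, the filters on spots and the handling of repeated spots are not given in the sources used here. Scale, centring and direction of the deposited log2 ratios are not stated. The base is taken as 2 because limma uses it and because the values run from -7.161 to 5.207. The array medians are close to 0, with values of 7e-04, -0.00059, 0.0012, 0.00243, 0.00092, -0.00118, -0.00204 and 0.00224 for arrays 1 to 8, so each array appears centred. Whether anything was done between arrays remains unknown, and the direction, Cy5 over Cy3, is likely from the order of the titles and from limma. With the opposite direction every log2 fold change turns its sign and no call changes.

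The table has 43603 probes and 0 missing values. In the platform annotation 23717 probes (54.4%) have 1 gene symbol, 0 have several and 19886 are unnamed here. The gene numbers of 23534 of the named probes were found in a RefSeq gene table of assembly GRCz12tu, with the same symbol for all 23534, and no coordinates were used from it. The named probes stand for 15554 genes, 9450 of them with 1 probe and 6104 with 2 or more, up to 10. A gene's value on an array is the median of its probes. The authors' scanner intensities are not used here, so signal over background is not known.

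For each gene, the 8 log2 ratios were solved by least squares for the levels of the 7 RNA samples plus a dye intercept of the gene. The levels were fitted with limma (lmFit and eBayes, version 3.58.1 in R 4.3.3) with a mean for each of 4 groups, namely 0, 1 and 5 µM at day 28 and 0 µM at day 4. The fit has 3 residual degrees of freedom and a prior of 1.34. RNA samples, not arrays, were thus the units, and all groups shared 1 spread. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The comparisons were 5 with 0 µM, 1 with 0 µM and 5 with 1 µM at day 28, an F test over the 3 doses, and day 28 with day 4 without cadmium. Since the levels come from shared arrays, the variance that array noise gives a difference was compared with the variance the fit assumes. It was 0.679, 0.632 and 0.694 of it for the dose comparisons, and 1.3 times it for day 28 with day 4. The variance ratio of RNA sample to array, estimated once over all genes for the generalized fit, was 0.0403. By that estimate array noise dominates, which by itself would make the p-values of single genes too small for day 28 with day 4 and too large for the doses. For day 28 with day 4 the observed count of genes at an unadjusted p under 0.05 nonetheless lay below chance.

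Before the data were examined, 24 gene lists were fixed, 16 for pathways and 8 for cell types that liver samples can hold. The ribosomal and respiratory chain lists were fixed as patterns of gene symbols, the others as symbols. The pathway lists were metal binding and transport, glutathione and oxidative stress, heat shock, endoplasmic reticulum stress, xenobiotic metabolism, acute phase and complement, vitellogenins and estrogen response, lipid and sterol metabolism, glycolysis with gluconeogenesis and glycogen, p53 with growth arrest and immediate early genes, cell cycle and DNA replication, proteasome, cytosolic ribosomal proteins, respiratory chain, circadian clock, and nuclear receptors with hormone axes. The cell type lists were hepatocyte, pancreas, erythrocyte, leukocyte and macrophage, intestine and bile ducts, endothelium and stroma, ovary and germ cells, and skeletal muscle. Each list was set against the other genes with camera of limma at a preset correlation of 0.01, adjusted over the 24 lists of a comparison, and again with a correlation estimated from the residuals, under which no list passed in any comparison.

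The rule for named genes was also fixed then. It takes genes past the threshold, then up to 6 more per direction with the lowest unadjusted p, leaving out names that are only clone identifiers, then up to 4 members of a list with the widest change, and a set of genes known from cadmium work. Since no gene passed, the named genes are those with the lowest unadjusted p, given as values. Of the list members, 2 or 3 per list are given, for the lists that passed and for those linked to stress, hormones, clock and glycolysis. Where leaving out 1 RNA sample kept the direction of a named gene but left under 2/3 of its change, the value is printed; this was chosen after seeing the data, as were the values with array 7 turned or its RNA samples swapped. At 1 µM the members named for the ovary and cell cycle lists are those chosen by the rule at 5 µM.

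The fit was tested on simulated data with 7 samples, variances drawn from the fitted prior and known changes in the comparison of 5 with 0 µM. In 10 runs of 15554 genes, it recovered 60.6% of 670 genes changed by 1 on the log2 scale, 87.5% of 670 changed by 2 and 95.8% of 660 changed by 4, with 67 false calls. For camera, a list of 40 genes moved by 0.3 was called in 50 of 50 runs with the preset correlation and in 41 with an estimated one, and an unmoved list was called in 1 and 0 of these runs. The simulated genes vary independently of each other. Their sample spread comes from the solved levels, which already hold array noise, and their array noise was set to the median residual SD, 0.0752. That division differs from the ratio of 0.0403 estimated for the data, so the recovered shares may not hold for these arrays.

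The alternatives fixed before the data were examined were no dye intercept, array-level fits (ordinary and generalized least squares), the replicate number as a block, the mean of a gene's probes, each probe by itself, centring and scaling of each array, leaving out the flattest genes, robust eBayes, the day 28 samples alone, leaving out each RNA sample and each array, and the opposite direction. Chosen after seeing the data were restriction to the 5451 genes whose loop closes (under 10% of the sum of squares left without a dye term), restriction to the 850 of these with a log2 ratio beyond 1, leaving out the pair of samples highest in ovary markers, turning array 7, and lists without each RNA sample. For the correlation between doses, 100 sets of unchanged groups were simulated, and 100 more with 1 control. Genes whose loop closes vary more between samples (median standard deviation 0.133 against 0.0686), since closure is a share of a gene's own sum of squares, so that restriction also selects for change. Other splits of the samples were not drawn because no group has more than 2 samples.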

Results

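Liver RNA of zebrafish (Danio rerio) was profiled on 8 two-colour oligonucleotide arrays. The labels name 7 RNA samples: day 28 at 0, 1 and 5 µM cadmium, with 2 biological replicates per dose, and day 4 at 0 µM, with 1. Cadmium is a toxic metal that collects in liver. Each array set a pair of these samples against each other, with 1 labelled in Cy5 (red) and 1 in Cy3 (green), and the arrays joined the 7 samples in a closed loop with 1 extra array between 0 µM replicate 2 and 5 µM replicate 1. The title of the series says that the experiment served to choose probes for a custom array, so the questions taken from the labels are which genes differ with cadmium dose at day 28 and which differ between day 28 and day 4 without cadmium. Each array held a log2 ratio for 43603 probes. The arrays' medians lay between -0.00204 and 0.00243, and their standard deviations between 0.2296 and 0.4086. The number of arrays and of RNA samples limits the precision. Nothing in the labels says whether a replicate was 1 fish or a pool. The p-values of single genes thus measure the spread between the solved levels of these samples, which holds array noise too. By the variance ratio of 0.0403 given above, array noise dominates that spread. The camera p-values at the preset correlation set a list against the other genes, with its members taken as nearly independent. They do not measure how a list as a whole varies between RNA samples. All directions assume that the ratio is Cy5 over Cy3, which is likely because the titles name the Cy5 sample first and limma, the tool named by the submitters, gives red over green.

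At 5 µM cadmium, genes of lipid and sterol metabolism rose as a group against 0 µM at day 28: 51 of the 73 measured members lay higher and 22 lower, with a median log2 fold change of 0.10 (camera with a preset correlation, adjusted p = 2.8e-07; adjusted p = 0.735 with an estimated correlation). The members with the widest change were cpt1b, fabp7a and acadvl. cpt1b, an enzyme of the pathway that brings long-chain fatty acids into mitochondria, was 4.30 times as high at 5 µM. fabp7a, a fatty acid binding protein, lay at a log2 fold change of 1.82 ± 0.62 (SE, n = 2 RNA samples per dose), and acadvl, which starts the oxidation of very long chains, at 1.55 ± 0.34. Without 0 µM replicate 2, fabp7a lay at 0.94. The group's median was 0.04 without 0 µM replicate 2 (adjusted p = 0.0046), and the group passed without each of the other samples too.

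Pancreas genes and cell cycle genes fell as groups at 5 µM, and each of these calls rested on single samples. Of 27 genes of exocrine and endocrine pancreas, 22 were lower and 5 higher, with a median of -0.39 (camera, adjusted p = 0.0065; adjusted p = 0.735 with an estimated correlation). Trypsin prss1 lay at -1.24 ± 1.16 and the chymotrypsin-like ctrl at -1.13 ± 0.54, while amy2al1, an amylase, lay at 1.05 ± 0.12. Without 0 µM replicate 2 the median of the pancreas genes was -0.08 and without 5 µM replicate 2 it was -0.07, and neither passed (adjusted p = 0.835 and 0.861); without 5 µM replicate 1 it was -0.65, and without both samples highest in ovary markers, a setting chosen after seeing the data that leaves 1 sample per dose, 0.04 (adjusted p = 0.343). Of 69 cell cycle and DNA replication genes, 56 were lower and 13 higher, with a median of -0.10 (camera, adjusted p = 0.0326; adjusted p = 0.735 with an estimated correlation). Examples are the microtubule regulator stmn1a at -0.91 ± 0.92, the survivin gene birc5b at -0.90 ± 1.00 and the replication helicase subunit mcm2 at -0.79 ± 0.89. The cell cycle median turned to 0.11 without 0 µM replicate 2 and to 0.14 without 5 µM replicate 1, each past the threshold (adjusted p = 0.0352 and 0.00498), and was -0.41 without 0 µM replicate 1 and -0.49 without 5 µM replicate 2. In the absence of both samples highest in ovary markers it stayed lower, at -0.14 (adjusted p = 0.00202). stmn1a turned to 0.18 without 5 µM replicate 1, birc5b to 0.10 without 0 µM replicate 2, and mcm2 to 0.26 and 0.0052 without these samples in turn. Others kept their direction but not their size. In the absence of 0 µM replicate 2, prss1 lay at -0.59 and stmn1a at -0.10, and without 5 µM replicate 1 birc5b lay at -0.0427.

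Ovary and germ cell markers moved with the cell cycle genes across the samples. The median level of 30 ovary markers, on a log2 scale with each gene's mean at 0, was 1.38 in 0 µM replicate 2 and 0.81 in 5 µM replicate 2, against -0.42 in 0 µM replicate 1, -0.67 and -0.14 in the 1 µM samples, -0.59 in 5 µM replicate 1 and 0.08 at day 4. The median of the cell cycle genes was 0.45 and 0.36 in the same pair of samples and between -0.31 and 0.03 in the other 5. In the comparison of 5 with 0 µM, 27 of the ovary markers were lower and 3 higher, with a median of -0.19, and the group did not pass (camera, adjusted p = 0.139); with array 7 turned it did (median -0.32, adjusted p = 0.00617). zp3, an egg envelope protein, lay at -1.45 ± 1.12, at -0.33 without 0 µM replicate 2 and at -0.56 without 5 µM replicate 1.

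**Figure D1:**
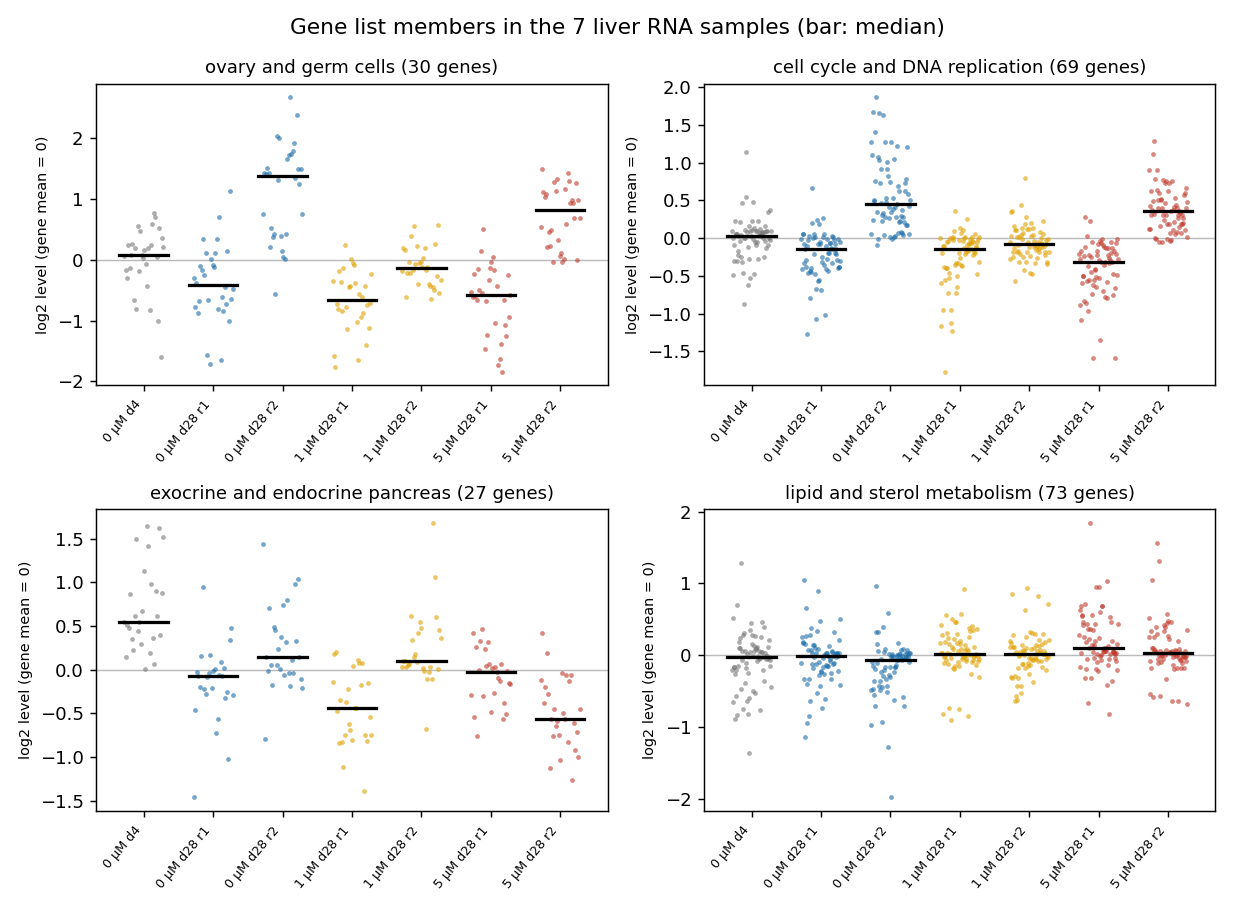
Log2 levels of the members of 4 gene lists in the 7 liver RNA samples; each point is 1 gene with its mean over the samples set to 0, and each bar is the median of the list. The medians of the ovary list are 1.38 in 0 µM replicate 2 and 0.81 in 5 µM replicate 2, above those of the other 5 samples.

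With array 7 as labelled, cytosolic ribosomal protein genes rose as a group at 5 µM, with 57 of 82 higher, 25 lower and a median of 0.12 (camera, adjusted p = 0.00635; adjusted p = 0.735 with an estimated correlation). Their widest differences went both ways: rplp0 lay at -0.97 ± 1.03, rps3 at -0.97 ± 0.36 and rps2 at 0.89 ± 1.13. The ribosomal median was -0.0168 without 0 µM replicate 1 and 0.06 without 5 µM replicate 1, and neither passed (adjusted p = 0.725 and 0.819). It was 0.27 without 0 µM replicate 2 and 0.23 without 5 µM replicate 2. The direction of array 7 is open, and so is that of this group. With array 7 turned, a setting chosen after seeing the data, the ribosomal median was -0.0177 (adjusted p = 0.743) and rps2 lay at 0.15. With the RNA samples of array 7 swapped they were 0.0185 and 0.17. Without 5 µM replicate 2, rplp0 turned to 0.47 and rps2 to -0.09, and without 0 µM replicate 1 rps2 turned to -0.45. rplp0 lay at -0.51 without 0 µM replicate 1 and rps3 at -0.46 without 5 µM replicate 2. Xenobiotic metabolism genes rose as a group, with 40 of 62 higher, 22 lower and a median of 0.03 (camera, adjusted p = 0.0065; adjusted p = 0.735 with an estimated correlation). The cytochromes P450 cyp2k6 and cyp2k18 lay at 1.66 ± 0.72 and 0.89 ± 0.31, and the glutathione transferase mgst1.2 at 1.13 ± 0.57. In the absence of 5 µM replicate 1, cyp2k6 lay at 0.73 and mgst1.2 at 0.68, and in that of 0 µM replicate 2, mgst1.2 lay at 0.44 and cyp2k18 at 0.48. The xenobiotic call was lost without 0 µM replicate 2 (median 0.0053, adjusted p = 0.721) and without 5 µM replicate 1 (median 0.0067, adjusted p = 0.805). The median was 0.08 without 0 µM replicate 1 and 0.07 without 5 µM replicate 2. Genes of vitellogenins and estrogen response rose as a group, with 10 of 16 higher, 6 lower and a median of 0.06 (camera, adjusted p = 0.0189; adjusted p = 0.735 with an estimated correlation). The aspartic protease nots lay at 1.32 ± 0.38 and the yolk precursor vtg5 at 1.08 ± 1.12, with a level of 1.67 in 5 µM replicate 1 and -0.14 in 5 µM replicate 2, and its change was 0.18 without 5 µM replicate 1 and -0.17 with array 7 turned (0.15 with its RNA samples swapped). This list also holds the egg envelope genes zp2.1, zp2.2, zp2.3, zp3 and zp3b, which are in the ovary list too. The call was lost without 0 µM replicate 1 (median 0.26, adjusted p = 0.533), without 5 µM replicate 1 (median 0.19, adjusted p = 0.185) and with array 7 turned (median 0.0427, adjusted p = 0.379), and the median was 0.64 without 0 µM replicate 2 and 0.43 without 5 µM replicate 2.

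The lists usually linked to cadmium did not pass at 5 µM. Of 28 genes of metal binding and metal transport, 13 were higher and 15 lower, with a median of -0.02 (camera, adjusted p = 0.434). The hepcidin gene hamp, a regulator of iron, lay at -0.81 ± 1.09 and the zinc exporter slc30a1a at -0.42 ± 0.37. Of 43 glutathione and oxidative stress genes, 20 were higher and 23 lower, with a median of -0.03 (adjusted p = 0.42). Catalase, cat, lay at 1.35 ± 0.38 and gpx4a, which reduces lipid peroxides, at 1.34 ± 0.30. The heme oxygenase hmox1a lay at -0.14 ± 0.34 and gclc, of glutathione synthesis, at -0.03 ± 0.23. Heat shock and chaperone genes were 19 higher and 25 lower of 44, with a median of -0.0152 (adjusted p = 0.513), and hspa4b lay at -1.32 ± 0.79, the heat shock factor hsf2 at -0.85 ± 0.09 and hsp70l at -0.16 ± 0.10. Genes of endoplasmic reticulum stress were 25 higher and 15 lower of 40, with a median of 0.05 (adjusted p = 0.42). The glutathione-degrading chac1 lay at 0.92 ± 0.24, the stress transcription factor atf3 at -0.53 ± 0.12 and the chaperone hspa5 at -0.14 ± 0.66. cyp1a, the main enzyme induced by aryl hydrocarbons, lay at 0.66 ± 0.32. Leaving out 1 sample turned 5 of these genes: without 0 µM replicate 1, hmox1a lay at 0.03, slc30a1a at 0.06 and hamp at 0.41; without 5 µM replicate 2, hmox1a at 0.30 and hamp at 0.22; without 0 µM replicate 2, hspa5 at 0.53 and gclc at 0.18; without 5 µM replicate 1, hspa5 at 0.56 and gclc at 0.09. Others shrank. slc30a1a fell to -0.20 and hspa4b to -0.55 without 5 µM replicate 2, and hspa4b to -0.78 without 0 µM replicate 1. cyp1a fell to 0.37 and hsp70l to -0.0661 without 5 µM replicate 1, and hsp70l to -0.0764 without 0 µM replicate 2. With the RNA samples of array 7 swapped, hamp lay at -0.51, chac1 at 0.55 and hmox1a at -0.0906. The metallothionein gene mt2 and the vitellogenin gene vtg1 were not among the named genes of the array.

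The other lists did not pass in the comparison of 5 with 0 µM. Nuclear receptor and hormone axis genes were 22 higher and 12 lower of 34 (median 0.03, camera, adjusted p = 0.129); among them fkbp5, a co-chaperone of the glucocorticoid receptor, lay at 1.87 ± 0.39 and the growth factor binding protein igfbp1b at -0.92 ± 0.55. Circadian clock genes were 16 higher and 19 lower of 35 (median -0.0189, adjusted p = 0.293), with the repressor bhlhe40 at -1.35 ± 0.46 and nfil3-5 at 0.87 ± 0.43. Glycolysis, gluconeogenesis and glycogen genes were 17 higher and 38 lower of 55 (median -0.05, adjusted p = 0.0591), with pgm1 at -0.96 ± 0.69, gpia at -0.94 ± 0.66 and gapdhs at -0.52 ± 0.05. Leaving out 5 µM replicate 2 put igfbp1b at -0.14, pgm1 at -0.0583 and gpia at -0.55. Leaving out 0 µM replicate 1 put bhlhe40 at -0.81, and leaving out 0 µM replicate 2 put nfil3-5 at 0.28. Acute phase and complement genes were 39 higher and 29 lower of 68 (median 0.08, adjusted p = 0.241). The p53, growth arrest and immediate early genes were 22 higher and 31 lower of 53 (median -0.0147, adjusted p = 0.905). Proteasome genes were 29 higher and 20 lower of 49 (median 0.04, adjusted p = 0.293), and respiratory chain genes 43 higher and 49 lower of 92 (median -0.0115, adjusted p = 0.969). Among markers of cell types, those of hepatocytes were 11 higher and 8 lower of 19 (median 0.07, adjusted p = 0.42), of erythrocytes 5 higher and 12 lower of 17 (median -0.04, adjusted p = 0.641) and of leukocytes and macrophages 13 higher and 19 lower of 32 (median -0.02, adjusted p = 0.189). Markers of intestine and bile ducts were 6 higher and 17 lower of 23 (median -0.04, adjusted p = 0.641), of endothelium and stroma 19 higher and 15 lower of 34 (median 0.0064, adjusted p = 0.357), and of skeletal muscle 14 higher and 12 lower of 26 (median 0.0040, adjusted p = 0.42). The median and the direction of the test differed in sign for the metal, glutathione, p53 and respiratory chain lists, and the mean and the test for the metal, p53, proteasome and respiratory chain lists; none of these passed.

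Gene by gene, limma called 0 of 15554 genes between 5 and 0 µM at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 384 genes, 206 higher and 178 lower, where chance gives 778. With each array centred and scaled there were 764, 415 higher and 349 lower. The array-level fit, which takes the 8 arrays as the units, called 2 genes and had 1722 at an unadjusted p under 0.05; the array-level generalized least squares fit called 2 and had 1453. Both fits called elovl2, which elongates polyunsaturated fatty acids, and znf395b (adjusted p = 0.0323 for each in the generalized fit). In the ordinary array-level fit their log2 fold changes were 0.96 ± 0.05 and -0.95 ± 0.05 (adjusted p = 0.0245 for each), against 0.90 ± 0.08 and -0.93 ± 0.08 on the level of RNA samples (adjusted p = 1). Of the genes with the lowest unadjusted p, the higher ones at 5 µM were also grb2b, an adaptor of growth factor receptors (1.00 ± 0.08, and 0.65 with the RNA samples of array 7 swapped), kdelr2b, a receptor that returns proteins to the endoplasmic reticulum (0.79 ± 0.09), rnf128a, a ubiquitin ligase (0.63 ± 0.08), and cmtm6 (0.40 ± 0.04). The lower ones were also ucp1, a mitochondrial carrier (-1.29 ± 0.16), cnot4b (-0.67 ± 0.09) and the RNA binding rbm4.3 (-0.63 ± 0.07), with hsf2 and gapdhs. Adjusted over the list alone, 1 gene passed in each of 4 lists, namely hsf2 among heat shock genes, elovl2 among lipid genes, gapdhs among glycolysis genes and amy2al1 among pancreas genes, and 0 in each of the other lists; over all genes tested, none of the 4 passed. Leaving out array 5, the only array between a 5 µM sample and 0 µM replicate 2 besides array 8, turned the direction of cmtm6, amy2al1, rnf128a, rbm4.3, gapdhs and 10 other genes named for this comparison.

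**Figure D2:**
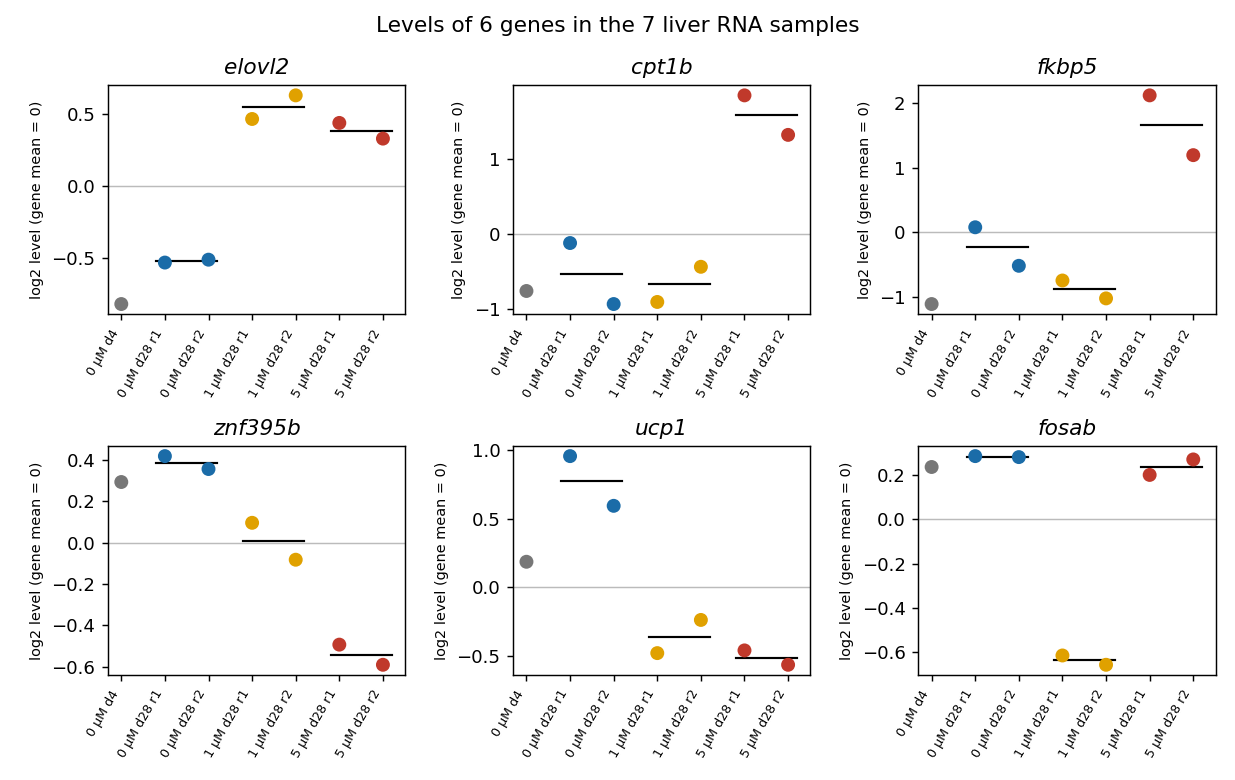
Log2 levels of 6 genes in the 7 liver RNA samples, with each gene's mean set to 0; points are RNA samples and the lines are means of the 2 samples of a dose at day 28. The levels of cpt1b are 1.84 and 1.31 at 5 µM and between -0.93 and -0.12 in the other 5 samples.

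At 1 µM cadmium against 0 µM, ovary and germ cell markers fell as a group, with 29 of 30 lower, 1 higher and a median of -0.77 (camera, adjusted p = 2.05e-05; adjusted p = 0.755 with an estimated correlation). zp3 lay at -1.83 ± 1.12 and zp3a.2, of the same egg envelope family, at -1.46 ± 0.58. Cell cycle and DNA replication genes fell with them, with 62 of 69 lower, 7 higher and a median of -0.25 (adjusted p = 3.35e-05; adjusted p = 0.755 with an estimated correlation), stmn1a at -0.50 ± 0.92 and birc5b at -0.97 ± 1.00. Both calls rested on 0 µM replicate 2, the sample with the highest ovary marker level: without it the ovary median was 0.06 (adjusted p = 0.931) and the cell cycle median 0.03 (adjusted p = 0.701). Without both samples highest in ovary markers the cell cycle median was 0.03 too, and the list passed as higher (adjusted p = 0.0121). Without 0 µM replicate 1 the ovary and cell cycle medians were -1.87 and -0.62, and without 1 µM replicate 1 the ovary median was -0.44. In the absence of 0 µM replicate 2, stmn1a lay at 0.30, birc5b at 0.03 and zp3 at -0.71. In that of 1 µM replicate 1, zp3 lay at -0.998, zp3a.2 at -0.62 and birc5b at -0.31.

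Lipid and sterol genes rose as a group at 1 µM too, with 54 of 73 higher, 19 lower and a median of 0.08 (camera, adjusted p = 0.000277; adjusted p = 0.755 with an estimated correlation). The call was lost without 0 µM replicate 2 (median 0.06, adjusted p = 0.12), and the median was 0.04 with the RNA samples of array 7 swapped. With array 7 as labelled, ribosomal protein genes rose, with 59 of 82 higher, 23 lower and a median of 0.12 (adjusted p = 0.000689; adjusted p = 0.755 with an estimated correlation). Their median, without 0 µM replicate 1, was -0.0013 (adjusted p = 0.983), without 1 µM replicate 1 it was 0.05, and without 0 µM replicate 2 it was 0.23. It turned to -0.18 with array 7 turned (adjusted p = 0.0673) and to -0.0742 with its RNA samples swapped, so the direction stays open. Proteasome genes rose, with 30 of 49 higher, 19 lower and a median of 0.08 (adjusted p = 0.0164; adjusted p = 0.755 with an estimated correlation); the call was lost without 0 µM replicate 2 (median -0.0133, adjusted p = 0.93), without 1 µM replicate 2 (median 0.08, adjusted p = 0.337) and with array 7 turned (median 0.07, adjusted p = 0.371), and the median was 0.17 without 0 µM replicate 1. Xenobiotic metabolism genes rose, with 43 of 62 higher, 19 lower and a median of 0.05 (adjusted p = 0.0197; adjusted p = 0.755 with an estimated correlation). That call was lost without 0 µM replicate 2 (median -0.0022, adjusted p = 0.931), without 1 µM replicate 1 (median 0.03, adjusted p = 0.23), without 1 µM replicate 2 (median 0.06, adjusted p = 0.0771) and with array 7 turned (median 0.04, adjusted p = 0.0636), and the median was 0.11 without 0 µM replicate 1. Glycolysis, gluconeogenesis and glycogen genes fell, with 36 of 55 lower, 19 higher and a median of -0.06 (adjusted p = 0.0354; adjusted p = 0.755 with an estimated correlation). That call was lost without 0 µM replicate 1 (median -0.04, adjusted p = 0.175), without 0 µM replicate 2 (median -0.07, adjusted p = 0.0802), without 1 µM replicate 2 (median -0.03, adjusted p = 0.427) and with array 7 turned (median -0.0077, adjusted p = 0.65). The other 17 lists did not pass.

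Gene by gene, limma called 0 genes between 1 and 0 µM. At an unadjusted p under 0.05 there were 213, 137 higher and 76 lower, where chance gives 778. With the replicate number as a block there were 512, 210 higher and 302 lower, so the balance of directions depends on the fit. The array-level fit called 1 gene, elovl2 (log2 fold change 1.09 ± 0.06, adjusted p = 0.0433), and had 787 at an unadjusted p under 0.05; the generalized least squares fit called 0 and had 700. On the level of RNA samples elovl2 lay at 1.07 ± 0.08 (adjusted p = 0.806). The immediate early gene fosab had the lowest adjusted p of the comparison, at -0.92 ± 0.05 (adjusted p = 0.44). Lower at 1 µM were also ucp1 (-1.14 ± 0.16), zfp36l1b, which promotes decay of messenger RNA (-1.10 ± 0.11), rbm4.3 (-0.58 ± 0.07), gbp (-0.52 ± 0.08) and the mitochondrial carrier slc25a25b (-0.37 ± 0.06). Higher were amy2al1 (0.77 ± 0.12), grb2b (0.62 ± 0.08), acy3.2 (0.61 ± 0.10), the cobalamin carrier tcn2 (0.52 ± 0.07) and taldo1, of the pentose phosphate pathway (0.43 ± 0.07). Adjusted over the list alone, elovl2 passed among lipid genes and fosab among immediate early genes, and 0 genes in each of the other lists. Leaving out array 2 turned the direction of grb2b, tcn2, acy3.2 and stmn1a, and leaving out array 7 that of grb2b. Most of these changes need array 7 as labelled. With it turned, grb2b lay at -0.0802, taldo1 at -0.0407, acy3.2 at 0.0259, tcn2 at 0.12, elovl2 at 0.34, fosab at -0.49, zfp36l1b at -0.26, ucp1 at -0.26, gbp at -0.27 and slc25a25b at -0.18. With its RNA samples swapped, grb2b lay at -0.25, tcn2 at -0.0328, acy3.2 at -0.018, taldo1 at 0.0214, elovl2 at 0.29, fosab at -0.41, zfp36l1b at -0.23, ucp1 at -0.26, gbp at -0.265, slc25a25b at -0.12 and rbm4.3 at -0.37.

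Between 5 and 1 µM no list passed in the main fit, and the ovary list had the lowest adjusted p at the preset correlation. With the replicate number as a block, the ovary and cell cycle lists passed. Of the 30 ovary markers, 28 were higher at 5 µM and 2 lower, with a median of 0.36 (camera, adjusted p = 0.0512, and 0.828 with an estimated correlation). This rise rested on 5 µM replicate 2, with a median level of 0.81. In 5 µM replicate 1 it was -0.59, between the -0.67 and -0.14 of the 1 µM samples. Genes of vitellogenins and estrogen response were 14 higher and 2 lower of 16, with a wider median, 0.38 (camera, adjusted p = 0.0566). That list shares zp2.1, zp2.2, zp2.3, zp3 and zp3b with the ovary list, so the lists are not separate results. Nuclear receptor and hormone axis genes were 20 higher and 14 lower of 34, with a median of 0.03 (camera, adjusted p = 0.0566). The glucocorticoid-linked fkbp5 was 5.79 times as high at 5 µM (log2 fold change 2.53 ± 0.39, adjusted p = 1). With the mean of a gene's probes, the ovary and the nuclear receptor lists passed (adjusted p = 0.0318 for each), and with array 7 turned 5 lists passed, with an ovary median of 0.49 (adjusted p = 8.38e-05). Leaving out any 1 sample of day 28 gave between 2 and 8 lists; without 5 µM replicate 2 the cell cycle genes were lower at 5 µM (median -0.20, adjusted p = 0.00538), and without 5 µM replicate 1 they were higher (median 0.46, adjusted p = 2.72e-10).

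limma called 0 genes between 5 and 1 µM. At an unadjusted p under 0.05 there were 282, 130 higher and 152 lower, where chance gives 778. With the replicate number as a block there were 424, 242 higher and 182 lower. The array-level fit called 0 and had 883 at an unadjusted p under 0.05, and the generalized least squares fit called 0 and had 799. fosab again had the lowest adjusted p (0.87 ± 0.05, adjusted p = 0.553): its level was 0.285 and 0.281 at 0 µM, -0.61 and -0.66 at 1 µM and 0.20 and 0.27 at 5 µM. Higher at 5 µM were also zfp36l1b (0.75 ± 0.11), slc25a25b (0.51 ± 0.06), the matrix protein gene tgfbi (0.46 ± 0.06) and pnrc2 (0.41 ± 0.07). Lower were cdc26, of the anaphase promoting complex (-0.64 ± 0.11), the astacin protease gene c6ast4 (-0.62 ± 0.10), znf395b (-0.55 ± 0.08), the mitochondrial co-chaperone grpel1 (-0.46 ± 0.06), tcn2 (-0.44 ± 0.07) and gapdhs (-0.41 ± 0.05). Adjusted over the list alone, fosab passed among immediate early genes, and 0 genes in each of the other lists. Leaving out 1 array turned the direction of c6ast4 and tcn2 (arrays 2 and 5) and of tgfbi (arrays 3, 4 and 6). With array 7 turned, zfp36l1b lay at 0.25 and tcn2 at -0.20, and with its RNA samples swapped fosab lay at 0.55, zfp36l1b at 0.22 and tcn2 at -0.11.

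For any difference among the 3 doses, the F test of limma called 0 genes, and 270 had an unadjusted p under 0.05; the array-level fit called 0 (smallest adjusted p = 0.052, 1205 at an unadjusted p under 0.05) and the generalized least squares fit called 0 (smallest adjusted p = 0.0665, 1027). Across the 15554 genes, which are not independent of each other, the changes at 5 µM and at 1 µM had a Pearson correlation of 0.618 and a Spearman correlation of 0.509. Both use the same 0 µM samples. Unchanged groups set against those controls gave 0.4998 on average in 100 simulations, between 0.4468 and 0.5498, and 0.4463 for Spearman, between 0.4238 and 0.4671, so both observed correlations lie above the simulated range. The covariance was 0.0279 against a simulated 0.0245, which is inside the simulated range of 0.0212 to 0.0285. The simulated groups share those controls too, so the simulated range already holds that part. The doses were not set against different controls, and the cause of the excess in correlation was not tested. Leaving out 0 µM replicate 1, the Pearson correlation was 0.8382 and the covariance 0.0888, and without 0 µM replicate 2 they were 0.7359 and 0.0456. Unchanged groups set against a single control gave 0.6676 and 0.0492 on average, with correlations between 0.6338 and 0.6965 and covariances between 0.0442 and 0.0549.

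Without cadmium, pancreas genes were lower at day 28 than at day 4 and fell as a group: 26 of 27 were lower and 1 higher, with a median of -0.55 (camera, adjusted p = 8.47e-08; adjusted p = 0.824 with an estimated correlation). The elastase gene ela2l lay at -1.85 ± 0.48, the serine protease gene zgc:92590 at -1.77 ± 0.48 and the trypsin gene prss59.2 at -1.62 ± 1.06. Day 4 is 1 RNA sample, which is assumed to vary like the other groups, and a difference between days is not separate from a difference between samples. The median level of the pancreas list was 0.54 at day 4 and -0.07 and 0.14 in the 0 µM samples of day 28. It was -0.44 and 0.10 in the 1 µM samples and -0.03 and -0.57 in the 5 µM samples. Replicates of 1 dose thus lay about as far apart as the days. The pancreas median was -0.30 without 0 µM day 28 replicate 1 (adjusted p = 2.69e-05) and the list passed without each other sample of day 28; prss59.2 lay at -0.59 without replicate 1 and at -1.06 with array 7 turned (-0.94 with its RNA samples swapped).

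Proteasome genes fell, with 34 of 49 lower at day 28, 15 higher and a median of -0.29 (adjusted p = 0.000137; adjusted p = 0.89 with an estimated correlation). psmb13a lay at -0.97 ± 0.27, psmb2 at 1.45 ± 1.03 and psmb4 at 0.95 ± 0.20. Genes of endoplasmic reticulum stress fell, with 27 of 40 lower, 13 higher and a median of -0.19 (adjusted p = 0.00141; adjusted p = 0.824 with an estimated correlation). The secreted stress protein manf lay at -1.37 ± 0.70, xbp1, a transcription factor of the unfolded protein response, at -1.34 ± 0.18 and the chaperone hsp90b1 at -1.14 ± 0.60. Leukocyte and macrophage markers fell, with 24 of 32 lower, 8 higher and a median of -0.07 (adjusted p = 0.0264; adjusted p = 0.89 with an estimated correlation); cd74b lay at -1.10 ± 0.34, ctss2.2 at -0.75 ± 0.35 and fcer1gl at -0.60 ± 0.37. Markers of intestine and bile ducts fell, with 18 of 23 lower, 5 higher and a median of -0.22 (adjusted p = 0.0346; adjusted p = 0.824 with an estimated correlation); epcam lay at -1.12 ± 1.25, krt92 at 0.90 ± 0.97 and fabp2 at -0.75 ± 0.36. Without 0 µM day 28 replicate 2 none of these 4 lists passed, with medians of -0.18 for proteasome (adjusted p = 0.0894), -0.23 for endoplasmic reticulum stress (adjusted p = 0.0975), -0.04 for leukocytes (adjusted p = 0.441) and -0.06 for intestine (adjusted p = 0.282). Without replicate 1 the leukocyte median was -0.12, and hsp90b1 lay at -0.75, psmb2 at 0.82, epcam at -0.025 and krt92 at 0.23. Without replicate 2, ctss2.2 lay at -0.33 and fcer1gl at -0.295. Both array-level fits turned the direction of epcam and krt92. The other 19 lists did not pass.

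limma called 0 genes between day 28 and day 4; 473 had an unadjusted p under 0.05, 222 higher and 251 lower, where chance gives 778, and the smallest adjusted p was 0.998. The array-level fit called 0 and had 698 at an unadjusted p under 0.05, and the generalized least squares fit called 0 and had 619. Of the genes with the lowest unadjusted p, the chemokine gene ccl19a.1 lay at -1.26 ± 0.14, mfap4.1 at -0.95 ± 0.12, the calpain subunit capns1b at -0.71 ± 0.10, selenof at -0.71 ± 0.10 and psmd4b, a ubiquitin receptor of the proteasome, at -0.56 ± 0.08, along with xbp1. Higher at day 28 were rdh1, a retinol dehydrogenase (1.39 ± 0.17), gbp (0.93 ± 0.10), aldh2.1, an aldehyde dehydrogenase (0.74 ± 0.11), rbm4.3 (0.71 ± 0.08), lpar2b, a receptor of lysophosphatidic acid (0.57 ± 0.08), and phf2 (0.55 ± 0.08). Adjusted over the list alone, 0 genes passed in each list. Leaving out array 2 or array 3 turned the direction of lpar2b, ccl19a.1, mfap4.1, hsp90b1, psmb13a and prss59.2, and leaving out array 4 or array 5 that of rbm4.3, rdh1, aldh2.1, xbp1, selenof, manf, psmb4 and zgc:92590.

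The loop allowed the arrays to be checked against each other. The route from 0 µM replicate 2 over 1 µM replicate 2 and 0 µM replicate 1 to 5 µM replicate 1 runs over arrays 6, 7 and 1, and array 8 measures the same difference directly. Array 7 is taken as labelled on this route, although its direction and its RNA samples stay open. Over 175 genes with a pair of probes that vary together, the sum over the route and the direct value had a correlation of 0.813 and a slope of 0.954; over all 15554 genes they had 0.562 and 0.868. With the loop solved for RNA sample levels and a dye term per probe, the median share of a probe's sum of squares left over was 5.2%. Unrelated ratios leave a median of 6.74%, so the typical probe closed little better than that. For the 3518 probes with a log2 ratio beyond 1 it was 2.32%. Different probes of a gene often disagreed: the median correlation over the arrays between the 2 most variable probes was 0.235, and the changes at 5 µM of the first 2 probes of a gene had a correlation of 0.351, or 0.635 for the 313 genes where both vary.

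**Figure D3:**
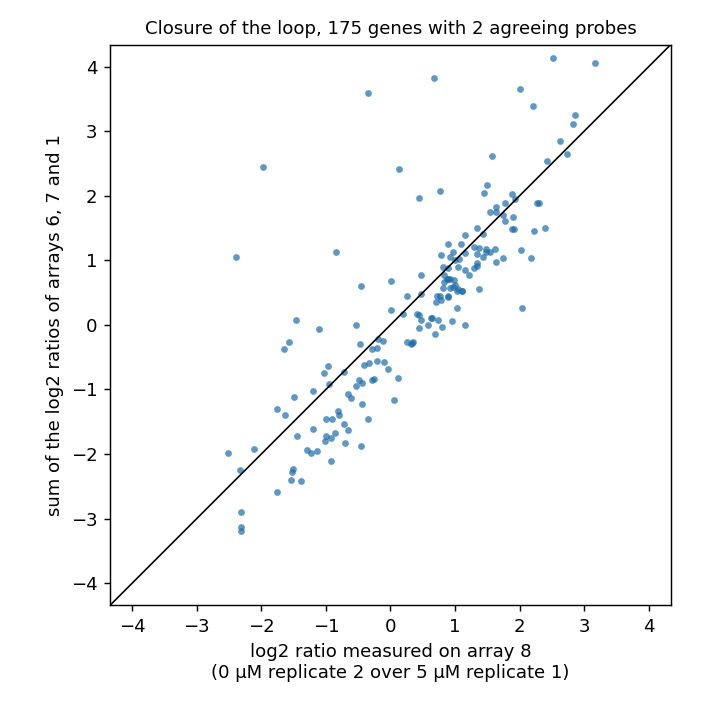
Closure of the loop for 175 genes with 2 agreeing probes; each point is 1 gene, the horizontal axis is the log2 ratio of 0 µM replicate 2 over 5 µM replicate 1 measured on array 8, and the vertical axis is the sum of the log2 ratios of arrays 6, 7 and 1. The diagonal marks equal values, and with array 7 as labelled the correlation is 0.813.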

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

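Restriction to the genes whose loop closes, leaving out the pair of samples highest in ovary markers, turning array 7, swapping its RNA samples and lists without each RNA sample were chosen after the results were seen. The count of called genes stayed at 0 in 144 of the settings tried over the 5 tests and moved in 5. The array-level fit called 2 genes at 5 against 0 µM and 1 at 1 against 0 µM, and the generalized least squares fit 2 at 5 against 0 µM; the ordinary fit takes the 8 arrays as units without a spread between samples, and the generalized one holds that spread as 1 variance ratio for all genes, 0.0403, rather than each gene's own. Among the 850 genes whose loop closes and that vary, 1 gene passed at 5 against 1 µM, ctsl.1 (-2.96, adjusted p = 0.0322), and 1 at day 28 against day 4, c7b (-3.68, adjusted p = 0.0249), each chosen after its value was seen; fewer genes were tested there. The level of c7b was 1.16 in 0 µM day 28 replicate 1, -3.59 in replicate 2 and 2.46 at day 4. Its change thus rested mostly on replicate 2. Requiring values on all 8 arrays removed nothing, and the correlation between doses over genes past the F test has no value, since no gene passed. Of the log2 fold changes, 2762 stayed on the same side with the same direction, 5 passed only under an alternative (elovl2 and znf395b in the array-level fits), 50 list medians lost their call and 107 turned direction. Without the Cy5 and Cy3 intensities, the limit that signal over background sets is not known.

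The replicate number as a block left 0 genes called in each test, with a smallest adjusted p of 0.366. In lists it gave 2 calls at 5 against 1 µM, ovary and cell cycle (adjusted p = 9.7e-07 and 0.00221), where there were 0. The vitellogenin list at 5 against 0 µM (adjusted p = 0.0652), glycolysis at 1 against 0 µM (0.0614), and leukocytes (0.0938) and intestine (0.0936) at day 28 against day 4 were not called with it; it changed no other call among the lists that passed. The deviations of same-numbered samples had correlations of -0.02 (0 and 1 µM), 0.645 (0 and 5 µM) and 0.018 (1 and 5 µM). The solved levels of same-numbered samples thus went together for 0 and 5 µM, but not for 1 µM with either dose. Arrays 1 and 5 each set same-numbered samples of 0 and 5 µM against each other. Array noise shared by their solved levels could add to that correlation, and its part was not tested. The main fit leaves the numbers out, and whether they mark a pairing is not given in the labels.

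With an estimated correlation the number of called lists was 0 at 5 against 0 µM, 0 at 1 against 0 µM and 0 at day 28 against day 4. Without each RNA sample in turn it ran from 5 to 10 at 5 against 0 µM, from 2 to 11 at 1 against 0 µM, from 2 to 8 at 5 against 1 µM, and from 3 to 8 at day 28 against day 4. The mean of the probes gave 2 lists at 5 against 1 µM. With array 7 turned there were 5 lists at 5 against 1 µM and 8 at day 28 against day 4, and without the pair highest in ovary markers 8 and 9. The medians of lists that turned with array 7 turned were those of ribosomal proteins, to -0.0177 at 5 against 0 µM and -0.18 at 1 against 0 µM. Without the pair highest in ovary markers, the pancreas median turned to 0.0424 at 5 against 0 µM, and at 1 against 0 µM those of xenobiotic metabolism to -0.0022, proteasome to -0.0133 and ovary to 0.0617, each without a call (adjusted p = 0.832, 0.675 and 0.0647), and that of cell cycle to 0.0306, which passed as higher (adjusted p = 0.0121). Without single samples, the medians ran from -0.49 to 0.14 for cell cycle, from -0.65 to -0.0689 for pancreas and from -0.0168 to 0.27 for ribosomal proteins at 5 against 0 µM. At 1 against 0 µM they ran from -0.0022 to 0.11 for xenobiotic metabolism, from -0.62 to 0.0306 for cell cycle, from -0.0133 to 0.17 for proteasome, from -0.0013 to 0.23 for ribosomal proteins and from -1.87 to 0.0617 for ovary. The cause of these turns was not tested, apart from what is weighed on ovary tissue.

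Leaving out an array of the large loop leaves 7 unknowns for 7 arrays, so the levels take up the noise of each array in full. This construction may be behind the turns without an array, which was not tested. The log2 fold changes of genes that turned are given here with both ends of their range, apart from scaled arrays, whose unit differs. At 5 against 0 µM without array 5 they were cmtm6 -0.44, amy2al1 -0.23, rnf128a -0.0865, rbm4.3 0.63, gapdhs 0.0568, hmox1a 0.57, hspa5 0.62, gclc 0.89, zp3 1.52, rplp0 3.95, rps2 5.93, prss1 1.88, hamp 1.06, hspa4b 0.0582, pgm1 1.38 and gpia 5.63. Without array 2 they were cmtm6 0.49, rnf128a 0.71, rbm4.3 -0.77, gapdhs -0.58 and gpia -1.67. They were, without 0 µM replicate 1, amy2al1 1.22, gclc -0.25, slc30a1a 0.0607, zp3 -2.57, birc5b -1.90, rps2 -0.45 and prss1 -1.89, and without 0 µM replicate 2 slc30a1a -0.90, birc5b 0.0983 and hamp -2.03. Without 5 µM replicate 1 they were hmox1a -0.58, stmn1a 0.18, mcm2 0.26, rplp0 -2.41, hspa4b -2.09 and pgm1 -1.86, and without 5 µM replicate 2 hspa5 -0.83, stmn1a -1.995 and mcm2 -1.83. The array-level fit turned hmox1a to 0.11 and generalized least squares to 0.0991. Without the pair highest in ovary markers, hmox1a was 0.14, gclc 0.0581 and rplp0 0.0189, and with array 7 turned vtg5 was -0.17; without array 5 it was 8.21.

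At 1 against 0 µM without array 2 the values were grb2b -1.22, tcn2 -0.43 and acy3.2 -0.57, and without array 3 grb2b 1.64, tcn2 1.04 and acy3.2 1.26. The values of stmn1a and birc5b were -1.30 and -1.97 without 0 µM replicate 1. After removal of 0 µM replicate 2, and likewise without the pair highest in ovary markers, stmn1a was 0.30 and birc5b 0.0327. With array 7 turned grb2b was -0.0802 and taldo1 -0.0407, and without array 3 taldo1 was 0.58. At 5 against 1 µM without array 3 the values were tgfbi -0.54, c6ast4 -1.14 and tcn2 -1.11, and without array 2 tgfbi 1.65, c6ast4 0.0054 and tcn2 0.36.

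At day 28 against day 4 without array 4 the values were rbm4.3 -0.82, rdh1 -0.16, aldh2.1 -1.78, lpar2b 1.54, ccl19a.1 -3.00, mfap4.1 -2.11, xbp1 0.58, selenof 0.56, manf 0.58, hsp90b1 -3.69, psmb13a -2.18, psmb4 -2.04, zgc:92590 0.0806 and prss59.2 -4.85. Without array 2 they were rbm4.3 1.99, rdh1 2.69, aldh2.1 2.87, lpar2b -0.26, ccl19a.1 0.20, mfap4.1 0.0308, xbp1 -2.95, selenof -1.78, manf -3.02, hsp90b1 1.01, psmb13a 0.0524, psmb4 3.47, zgc:92590 -3.32 and prss59.2 1.101. The array-level fit turned epcam to 0.12 and krt92 to -0.20, and generalized least squares turned them to 0.0622 and -0.15. Their other ends were -2.35 for epcam without array 4 and 1.58 for krt92 without 0 µM replicate 2; the cause was not tested.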

Other observations

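Tests of a more female liver, of cadmium dose, of dye bias on single arrays, of swapped RNA samples on array 7 and of a probe-specific dye effect were chosen only after the result was seen; the other 5 were written down before their values were computed.

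Ovary and germ cell markers stood highest in the same pair of day 28 samples, 0 µM replicate 2 and 5 µM replicate 2: 23 of 30 lay above all 5 other samples in both, against 11.3% of all genes and 4.76% for an even chance (22 of 30 and 10.9% with array 7 turned, 23 and 10.8% with its RNA samples swapped), and the pair was picked after these levels were seen. The linker histone h1m lay at 2.03 and 1.28 in them, org at 2.00 and 1.33, the germ cell gene dazl at 1.42 and 1.08 and the oocyte gene zar1 at 1.66 and 1.17. In 5 µM replicate 1 the yolk precursor vtg2 lay at 1.93 and vtg5 at 1.67, and in 1 µM replicate 2 at 0.77 and 1.59. The glucocorticoid-linked fkbp5 lay at 2.11 and 1.19 in the 5 µM samples and tsc22d3 at 1.03 and 0.26, with all other samples of tsc22d3 between -0.45 and -0.10. Other hormone axis genes went the other way. The growth factor binding protein igfbp1b lay at 0.17 and -1.39 in the 5 µM samples, against 0.20 and 0.42 at 0 µM of day 28. Of that list, 22 genes were higher and 12 lower at 5 against 0 µM, and it did not pass (camera, adjusted p = 0.129).

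The ovary pattern may come from ovary tissue or oocytes in that pair of RNA samples: a second oocyte list with no shared gene had a median difference of 0.744 between the pair and the other 5, with 17 of 20 genes above 0 (0.707 with array 7 turned). The arrays argue against a dye bias of the probes, which would not turn with the sample: over all 30 markers the median log2 ratio was 1.62 and 1.88 on arrays 6 and 8, with 0 µM replicate 2 in Cy5, and -0.60 on array 4, with 5 µM replicate 2 in Cy3. The 21 markers whose loop closes had a median difference of 1.75, which decides nothing on dye because that restriction selects for change. The 5 measured vitellogenins had a median difference of -0.298, with 0 above 0, but without 5 µM replicate 1 it was -0.0456, with 2 above 0, so a more female liver without ovary tissue stays open. Histology and the sex of the fish are not given in the sources used here, so a germ cell signal from another source was not tested.

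For the lipid genes that rose at 5 µM, ovary tissue in the control RNA could have lowered the share of liver RNA, and this stays open. Without the pair highest in ovary markers the median was 0.0794 (adjusted p = 3.29e-05), but that leaves 1 sample per dose; without 0 µM replicate 2 alone it was 0.0396, and at 1 µM the call was lost without the pair (0.0634, adjusted p = 0.201). Against a dye bias as the whole cause, array 5 minus the mean of arrays 1 and 8, in which such a bias cancels, gave a median of 0.124 over all 73 members when halved (95% interval 0.0492 to 0.314, with genes taken as independent). The 35 members whose loop closes had a median of 0.251, which decides nothing on dye for the reason given above. An effect that grows with cadmium dose stays open too (5 against 1 µM, median 0.0483, adjusted p = 0.191), and feeding or sex was not tested.

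Over all probes the 8 arrays fitted the loop better with array 7 turned, with 5.217% of the sum of squares left against 6.404% as labelled, and 14.2% against 20.23% without a dye term. Turning array 2 or array 3 also left less without a dye term, 18.42% and 19.59%, but not with one. Over the genes with 2 agreeing probes the labelled direction left less with a dye term, 2.297% against 2.831%, and more without one, 5.606% against 5.422%. A ratio of array 7 given as green over red stays open: among 45 genes with agreeing probes and a wide ratio on array 7, turning it left less in 16, or 35.6% (95% interval 21.9 to 51.2). Swapped RNA samples on that array stay open as well, with 13 genes, or 28.9% (16.4 to 44.3). Whether a probe-specific dye effect accounts for the better fit with array 7 turned stays open: a dye term lowered the median share left by a factor of 3.69, and unrelated ratios give 3.06 for medians. The halving named in the prediction holds only for means. For probes with a log2 ratio beyond 1 the share fell from 10.9% to 2.32%. The dye intercept was above 0.5 for 494 probes and below -0.5 for 36. That imbalance points to a dye effect in some probes, but does not say whether it accounts for the fit of array 7. No biological explanation was tested.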
